A study of Mus musculus with 6 samples.

How the data were processed

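Total RNA from the lungs of adult female F1 mice was measured on Affymetrix 3' expression arrays with biotin-labelled target, per the labels. The arrays fell into 2 groups of 3. In one group the mice came from a cross of AKR/J with FVB/NJ (AKR_F1 below), and in the other from a cross of DBA/2J with FVB/NJ (DBA_F1 below), so that both groups carried an FVB/NJ chromosome set and differed in the set from the other parent. Replicate numbers were taken from the sample titles. The labels do not say whether each array came from a separate animal, so the p-values given here measure the difference between the groups against the spread between these samples.

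The deposited values are on a log2 scale, 1 value per probe set and array. The submitters' processing notes name MAS5 and RMA and give no versions, and they do not say which of them made the table. The scale was therefore read from the values. The array medians were 5.47, 5.46 and 5.49 in AKR_F1 replicates 1 to 3 and 5.48, 5.48 and 5.46 in DBA_F1 replicates 1 to 3. The largest value on any array was 14.56 and the upper quartiles were nearly equal between arrays, which is the range of log2 signals scaled between arrays, and the values were not centred per gene. They were used as deposited, without further normalization. No detection calls were used, so low values have no stated limit of background, and the number of arrays limits the precision.

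After removal of 64 control probe sets, 45037 probe sets were left. Gene symbols came from the platform annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Of the probe sets with 1 symbol, 34741 were found by gene ID in a RefSeq gene table of the GRCm38.p6 assembly, which was used only for chromosomes and the order of genes. Probe sets with several symbols were not named. Probe sets in the lowest 40% by mean over all 6 arrays were left out (mean log2 of 4.72 or less), which left 27022 tested probe sets, 23172 of them with 1 symbol, for 13202 genes. A gene with several tested probe sets was represented by the one with the highest mean over all arrays, and its adjusted p is that of the fit over all tested probe sets.

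Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with group as the only term. All log2 differences are AKR_F1 minus DBA_F1, with the moderated standard error (SE). The fit had 4 residual and 3.06 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and a probe set was called at an adjusted p under 0.05. The 32 gene lists, with 532 genes in all, covered lung cell types, immune and MHC genes, xenobiotic metabolism, metastatic niche and modifier genes, known parental alleles, and tissues that lie near the lung. They were tested with limma's camera against all other tested genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, and fry, were run beside it. Members that pass are counted over all genes tested and also adjusted over the list alone.

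The lists, the tests, the filter and most alternatives were chosen before the data were examined. Genes are named by a rule also fixed then: among called genes whose groups do not overlap, the 12 with the largest difference in each direction, then up to 4 called members of each list, and members of the modifier and parental allele lists as needed. Other list members given as examples, and H2-D1, were chosen after their values were seen. Chromosomes were compared by Fisher's exact test. Pairs of neighbouring called genes were compared with 10000 random placements of the calls. The 3' to 5' signal of actin and Gapdh control probe sets was compared by an exact two-sided permutation test, whose smallest p for 3 against 3 arrays is 0.1.

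The fit was tested on simulated data with the means and spreads of these probe sets. Of the changed probe sets that were tested, it recovered 17 of 49 at a log2 difference of 0.5, 42 of 50 at 1, 48 of 48 at 2 and 48 of 49 at 3, with 2 false calls among 157. In the same simulation a shifted list had an adjusted p of 0.000834, and 0 other lists were called. The simulated values were independent between probe sets, so this cannot show how often lists of correlated genes are called wrongly. Nor can it show how often probe sets that shift together on an array are called wrongly. In the data the estimated correlation within a list ranged from -0.033 (circadian clock genes) to 0.99 (skeletal muscle genes).

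The alternatives were quantile normalization, median centring, no filter or a 60% filter, eBayes without a trend or with robust estimation, array weights, the replicate number as a block, leaving out each array, and other summaries of the probe sets of a gene. After the data were seen, 3 more were added, since transcripts of other tissues differed between arrays: the mean of the upper airway and oesophagus list as a covariate, the mean of the adipose list as a covariate, and AKR_F1 replicate 3 alone against the DBA_F1 arrays. In addition 3 further lists (skin and hair, further adipose and brown fat genes) were written for the closing section. On AKR_F1 replicates 1 and 2 the upper airway and oesophagus mean lay far below the other arrays. That covariate fit therefore rests largely on AKR_F1 replicate 3 against DBA_F1, and so do calls made only there. The adipose mean separated the groups completely, so as a covariate it takes up much of the group difference.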

Results

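Lung expression was compared between adult female (AKR/J × FVB/NJ)F1 mice and (DBA/2J × FVB/NJ)F1 mice, with 3 arrays per group, to find basal differences between the genotypes. AKR/J, DBA/2J and FVB/NJ are inbred strains, and every animal carried 1 set of chromosomes from FVB/NJ. Signals are log2 values for 27022 tested probe sets and 13202 genes. Pearson correlations between arrays across probe sets lay between 0.965 and 0.995. AKR_F1 replicates 1 and 2 correlated at 0.995 with each other. AKR_F1 replicate 3 correlated at 0.975 and 0.976 with them and at 0.984, 0.984 and 0.986 with the DBA_F1 arrays. The first principal component held 61.6% of the variance and placed AKR_F1 replicates 1 and 2 (scores of -40.0 and -39.2) apart from AKR_F1 replicate 3 (8.41) and the DBA_F1 arrays, which all scored above it.

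The largest differences with higher signal in AKR_F1 lung were those of Gm13306, the heparan sulphate proteoglycan syndecan-4 (Sdc4) and the epithelial serine protease Prss22. In DBA_F1 lung the largest were those of the gluconeogenic and glyceroneogenic enzyme Pck1, the hyaluronan scavenger receptor Stab2 and 6330403K07Rik. Adipocyte genes and an MHC class II alpha chain (H2-Ea) were also higher in DBA_F1, and surfactant protein B (Sftpb) was slightly higher in AKR_F1. In the limma fit 707 probe sets were called at an adjusted p under 0.05, 424 higher in AKR_F1 and 283 higher in DBA_F1, and 4974 had an unadjusted p under 0.05. Counted by representative probe set, 327 genes were called, 187 higher in AKR_F1 and 140 higher in DBA_F1. With 1 array left out this count ran from 83 to 656, the latter without AKR_F1 replicate 3 (274 higher in AKR_F1 and 382 in DBA_F1). Array weights gave 592 genes. The median absolute difference of called genes was 0.55 log2, and 42 genes differed by more than 1 log2, 16 higher in AKR_F1 and 26 higher in DBA_F1. In all 707 called probe sets the groups did not overlap, as in 23.6% of all tested probe sets, against 10% by chance. The count of called probe sets was 198 without AKR_F1 replicate 1, 199 without AKR_F1 replicate 2, 249 without DBA_F1 replicate 2 and 1171 without AKR_F1 replicate 3 (561 higher in AKR_F1 and 610 in DBA_F1). Without DBA_F1 replicate 3 it was 713, with 284 higher in AKR_F1 and 429 in DBA_F1. In alternatives added after the data were seen, the sign of all 707 was kept with either covariate. The upper airway and oesophagus covariate fit rests largely on AKR_F1 replicate 3 against DBA_F1. The lack of overlap therefore largely fixes its signs in advance. The count of called probe sets was 188 with the mean of the upper airway and oesophagus list as a covariate. It was 13 with the mean of the adipose list as a covariate. It was 85 for AKR_F1 replicate 3 alone against DBA_F1, where the spread comes from the DBA_F1 arrays and the sign of the 707 is fixed by the lack of overlap.

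Among the 12 genes with the largest differences toward AKR_F1, Gm13306 had the largest measured difference (log2 3.73 ± 0.21 SE, 7.24 against 3.51, n = 3 per group, limma adjusted p = 0.000434). Sdc4 was 7.86-fold higher (2.97 ± 0.085, adjusted p = 1.95e-05) by its brightest probe set, while its other tested probe set differed by -0.34 (adjusted p = 0.21). Prss22 was 4.77-fold higher (2.25 ± 0.15), and Sirpb1a, a signal-regulatory protein of myeloid cells, was 3.50-fold higher (1.81 ± 0.070). The carbohydrate kinase Fggy differed by 1.65 ± 0.15 and the neuronal intermediate filament peripherin (Prph) by 1.25 ± 0.12. Tmem267 differed by 1.23, the phospholipase Plcb1 by 1.09, the zinc finger gene Zfp979 by 1.08, cytidine deaminase (Cda) by 1.08 and the protein O-mannosyltransferase Pomt1 by 1.07. The 3 other tested probe sets of Plcb1 differed by 0.11 to 0.45 and were not called, and the mean of its probe sets was not either (0.51, adjusted p = 0.0734). The DBA_F1 means of Gm13306, H2-Q10, Prph, Zfp979 and Cda lay below the filter level of 4.72, where signal is not separated from background, so the sizes of these differences and their ranks are not exact. The MHC class I gene H2-Q10 differed by 1.39 ± 0.21 (adjusted p = 0.0216). These calls were kept in each of the 6 fits that left out 1 array except for H2-Q10, whose adjusted p was 0.101 without DBA_F1 replicate 2, and Cda, at 0.0945 without AKR_F1 replicate 2. H2-Q10 was also lost without AKR_F1 replicate 1 or DBA_F1 replicate 1 and Cda without AKR_F1 replicate 1 or DBA_F1 replicate 3. With the upper airway and oesophagus covariate Cda was not called (0.135).

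Among the 12 genes with the largest differences toward DBA_F1, Pck1 had the largest measured difference (-3.58 ± 0.55 SE, 4.43 against 8.01, n = 3 per group, limma adjusted p = 0.0233). Stab2 differed by -3.41 ± 0.14 (adjusted p = 0.000101), and 6330403K07Rik was 6.08-fold higher in DBA_F1 (-2.60 ± 0.18). The AKR_F1 means of Pck1 and Stab2 (both 4.43) lay below the filter level of 4.72, so the sizes of these differences and their ranks are not exact. The extracellular matrix protein tenascin-N (Tnn) differed by -2.21 ± 0.098, H2-Ea by -2.04 ± 0.14, the RNA-binding protein Rbm45 by -2.02 ± 0.11 and E330020D12Rik by -1.84 ± 0.21. The fatty acid carrier Fabp4 (-1.87), the hormone adiponectin (Adipoq, -1.85) and the lipid droplet protein Cidec (-1.71) are made by adipocytes. The secreted iron-binding protein lactoferrin (Ltf, -1.74) and the cytochrome P450 Cyp2e1 (-1.50) completed the group. Stab2, 6330403K07Rik, Tnn, H2-Ea, Rbm45 and E330020D12Rik passed in each of the 6 fits that left out 1 array. With the upper airway and oesophagus covariate E330020D12Rik was not called (0.0631), nor were Pck1 (0.141), Fabp4 (0.187), Adipoq (0.175), Cidec (0.101) and Cyp2e1 (0.0915). Ltf, a member of the list behind this covariate, was not called either (0.22). Adjusted p rose to 0.0924 for Pck1, 0.166 for Fabp4, 0.118 for Adipoq, 0.0809 for Cidec and 0.0508 for Cyp2e1 without AKR_F1 replicate 2, and to 0.134 for Ltf without DBA_F1 replicate 2. Pck1 and Adipoq were also lost without DBA_F1 replicates 1 or 2, Fabp4 without any array but DBA_F1 replicate 3, and Ltf without DBA_F1 replicate 1 or AKR_F1 replicates 1 or 2. Pck1, Fabp4, Adipoq and Ltf were also not called with robust eBayes (0.0834, 0.127, 0.0858 and 0.0894), Fabp4 not without a trend (0.0586) and Ltf not with the replicate block (0.0538).

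**Figure D1:**
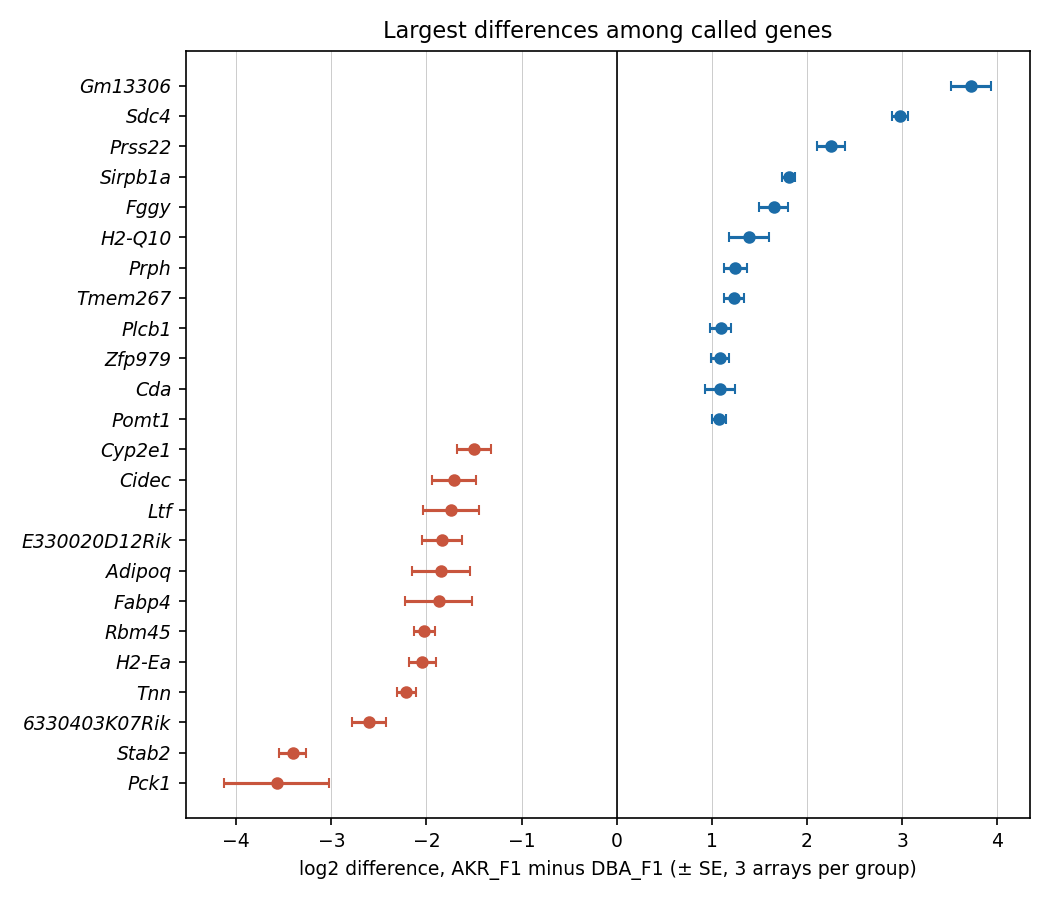
Log2 difference (AKR_F1 minus DBA_F1, horizontal axis) of the 12 called genes with the largest differences in each direction (vertical axis), as points with bars of 1 SE from limma. Gm13306 (3.73) and Pck1 (-3.58) lie at the ends, and Pck1, Fabp4, Adipoq and Ltf have the widest bars.

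Transcripts of squamous epithelium and striated muscle separated AKR_F1 replicates 1 and 2 from the other 4 arrays. Keratin 13 (Krt13) had a signal of 3.39 as the mean of AKR_F1 replicates 1 and 2, 12.13 in AKR_F1 replicate 3 and 12.06 ± 0.34 (SD, n = 3) in DBA_F1. Its partner keratin 4 (Krt4) had 4.72, 12.80 and 12.65, and the cornified envelope gene Sprr3 had 4.93, 10.53 and 10.39. Skeletal alpha-actin (Acta1) had 6.78, 13.12 and 12.65, and the fast myosin heavy chain Myh1 had 3.54, 10.77 and 10.23. The mean of the 12 upper airway and oesophagus genes was 5.61, 5.78 and 8.71 on AKR_F1 replicates 1 to 3 and 8.83, 9.18 and 8.51 on DBA_F1 replicates 1 to 3. Over all 6 arrays that list was lower in AKR_F1 by camera with a preset correlation (mean difference -2.14, adjusted p = 2.83e-05), and so were the 9 skeletal muscle genes (-2.59, adjusted p = 0.000688). With an estimated correlation the adjusted p was 0.709 for both. In the first list only Ltf passed over all genes (2 passed adjusted over the list alone), and 0 skeletal muscle genes passed by either count. The list mixes squamous genes with the gland and surface mucosa genes Ltf, Bpifb1 and Tff2, which did not follow Krt4 and Krt13 (Ltf was 8.26 in AKR_F1 replicates 1 and 2, 8.32 in AKR_F1 replicate 3 and 10.02 in DBA_F1). The keratin Krt6a did not follow them either (5.69, 5.72 and 5.76). The skeletal muscle mean difference was -4.13 without AKR_F1 replicate 3 and -1.71 without AKR_F1 replicate 2. For AKR_F1 replicate 3 alone against DBA_F1 the mean difference was -0.13 for the upper airway and oesophagus genes and 0.50 for the skeletal muscle genes, given as values without a test since 1 array has no spread of its own.

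**Figure D2:**
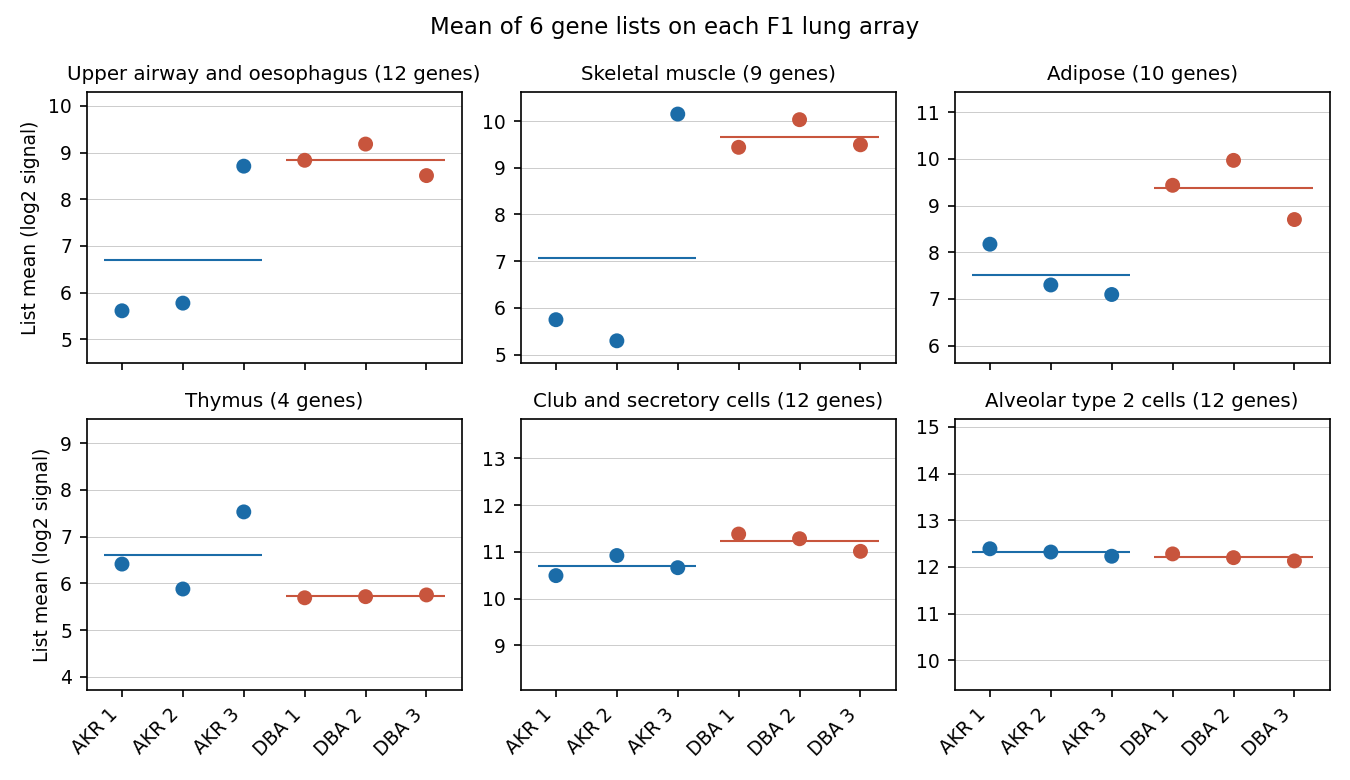
Mean log2 signal of 6 gene lists (vertical axes, each spanning the same range) on each array (horizontal axes), with AKR_F1 arrays in blue, DBA_F1 arrays in red and a line at each group mean. The upper airway and oesophagus mean of AKR_F1 replicate 3 (8.71) lies with the DBA_F1 arrays, whereas its adipose mean (7.10) lies with AKR_F1 replicates 1 and 2 (8.17 and 7.30).

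The adipose list mean was higher on every DBA_F1 array than on any AKR_F1 array. All 10 measured members had higher means in DBA_F1, with a mean difference of -1.84 (camera adjusted p = 4.33e-09, and adjusted p = 0.709 with an estimated correlation), and 4 passed over all genes (10 adjusted over the list alone). These were Pck1, Fabp4, Adipoq and the hormone leptin (Lep, -0.77, adjusted p = 0.0482). The call of Lep was lost in each fit that left out 1 array (adjusted p of up to 0.144 without AKR_F1 replicate 2). It was also lost under most other alternatives, among them the replicate block (0.106) and the covariates for upper airway and oesophagus (0.0907) and adipose genes (0.603). Lep is itself in the adipose list, so the loss with the adipose covariate is partly built in. The AKR_F1 mean of Lep, 4.50, lay below the filter level. The brown fat uncoupling protein Ucp1 had -4.26 ± 1.11 (adjusted p = 0.111), with a range from 3.82 in AKR_F1 replicate 3 to 11.25 in DBA_F1 replicate 2. The 4 tested probe sets of Fabp4 ranged from -1.87 to -1.39. With the mean of the upper airway and oesophagus list as a covariate, the adipose mean difference was -2.16. Oxidative phosphorylation genes moved the same way as a list, but not on every array. Their mean was 10.82, 10.82 and 10.84 on AKR_F1 replicates 1 to 3 and 11.15, 11.22 and 10.87 on DBA_F1 replicates 1 to 3. The mean difference was -0.36 without DBA_F1 replicate 3 and -0.18 without DBA_F1 replicate 2. All 22 measured members, among them cytochrome c (Cycs, -0.45 ± 0.10) and Uqcrc1 (-0.36 ± 0.11), had negative differences with a mean of -0.26 (adjusted p = 1.77e-09, and adjusted p = 0.709 with an estimated correlation). None of them passed over all genes, and 10 passed adjusted over the list alone. Their mean difference was 0.027 (adjusted p = 0.782) with the adipose mean as a covariate, which separates the groups completely.

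Some markers of the alveolar epithelium were slightly higher in AKR_F1. Among 12 alveolar type 2 markers the lysophospholipid acyltransferase Lpcat1 (0.41 ± 0.078, adjusted p = 0.0452), the aspartic protease napsin A (Napsa, 0.34 ± 0.064) and surfactant protein B (Sftpb, 0.32 ± 0.057) passed over all genes, and 5 passed adjusted over the list alone. For surfactant protein C (Sftpc, 0.02) the signal lay near the array maximum, which limits any difference. The mean difference was 0.11 for type 2 markers and 0.16 for 12 type 1 markers (camera adjusted p = 0.00606 for both, and adjusted p = 0.709 for both with an estimated correlation). The type 2 mean was 0.073 without AKR_F1 replicate 1 and also without DBA_F1 replicate 3. Of the type 1 markers 0 passed over all genes and 5 adjusted over the list alone, among them Vegfa (0.28 ± 0.074) and the chloride channel protein Clic5 (0.26 ± 0.073). The 16 endothelial markers had a mean of 0.13 (adjusted p = 0.00872, and adjusted p = 0.709 with an estimated correlation), with 0 passing over all genes and 4 adjusted over the list alone, namely Kdr (0.39), Flt1, Tek and Cldn5. Beside them, AKR_F1 replicate 3, with its squamous signal, had lower means than AKR_F1 replicates 1 and 2 by -0.12 (type 2), -0.15 (type 1) and -0.18 (endothelial), and with the upper airway and oesophagus mean as a covariate 0 of the 3 lists were called: the means were 0.031 (type 2, adjusted p = 0.135), 0.040 (type 1, adjusted p = 0.541) and -0.0084 (endothelial, adjusted p = 0.841). For AKR_F1 replicate 3 alone against DBA_F1 they were 0.028, 0.054 and 0.0089. Endothelial markers were not called without AKR_F1 replicate 1 or DBA_F1 replicate 1 (adjusted p = 0.0803 for the latter). Lpcat1, Napsa and Sftpb each lost the call without AKR_F1 replicates 1 or 2 or DBA_F1 replicates 2 or 3, with adjusted p of 0.172, 0.163 and 0.151 at the highest (without DBA_F1 replicate 2 for the first pair and AKR_F1 replicate 1 for Sftpb). Without a trend in eBayes they were not called either (0.0741, 0.0781 and 0.0782). With the mean of the probe sets of each gene Lpcat1 differed by 0.25 (adjusted p = 0.184) and Napsa by 0.27 (adjusted p = 0.105), and by its most variable probe set Lpcat1 was not called (0.0969).

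The airway secretoglobin Scgb3a1 was higher in DBA_F1 (-1.21 ± 0.21, adjusted p = 0.0323), and the airway defence genes Bpifa1 (-1.67 ± 0.36, adjusted p = 0.0677), Reg3g (-1.52 ± 0.61) and the mucin Muc5b (-0.77 ± 0.23) had the same sign. The 12 club and secretory cell markers had a mean difference of -0.54 and a median of -0.17 (camera adjusted p = 5.7e-06, and adjusted p = 0.709 with an estimated correlation), with 1 passing over all genes and 3 adjusted over the list alone. For the club cell secretoglobin Scgb1a1 (-0.059) the signal lay near the array maximum, which limits any difference. Ciliated cell markers had a mean of -0.12 (13 genes, adjusted p = 0.00899, and adjusted p = 0.709 with an estimated correlation), with 0 passing over all genes and 1, Tekt4, adjusted over the list alone. The ciliated mean was -0.19 without AKR_F1 replicate 2 and -0.075 without DBA_F1 replicate 1. Smooth muscle genes, which vessels, airways and the oesophagus share, had -0.33 (10 genes, adjusted p = 0.000205, and adjusted p = 0.709 with an estimated correlation), with 0 passing over all genes and 2, Cnn1 and Smtn, adjusted over the list alone. With the upper airway and oesophagus mean as a covariate the smooth muscle mean was -0.16 and not called (adjusted p = 0.138). With the same covariate the ciliated mean was -0.21 (camera adjusted p = 0.000758 with the preset correlation). That fit is close to AKR_F1 replicate 3 alone against DBA_F1 (-0.20), and the estimated correlation within this list was 0.65. Ciliated means of the groups overlapped, with 7.655 in AKR_F1 replicate 2 and 7.534 in DBA_F1 replicate 2. With array weights (0.0549) the ciliated list was not called, nor was it without AKR_F1 replicate 3 or DBA_F1 replicate 1 (0.108). Scgb3a1 had an adjusted p of 0.0818 with robust eBayes and 0.137 without DBA_F1 replicate 2, and was also lost without DBA_F1 replicate 1 or AKR_F1 replicates 1 or 2. With the upper airway and oesophagus covariate it differed by -1.18 and was not called (0.205). The adipose list mean was likewise higher on every DBA_F1 array than on any AKR_F1 array.

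MHC genes differed between the groups in both directions. AKR/J carries the k haplotype of this region, DBA/2J the d haplotype and FVB/NJ the q haplotype. H2-Ea was 4.12-fold higher in DBA_F1 by its brightest probe set (-2.04 ± 0.14, adjusted p = 0.000985) and differed by -3.88 by the other. The beta chain H2-Eb1 passed too (-0.81 ± 0.14, adjusted p = 0.0323), but was lost without any array other than AKR_F1 replicate 3 (0.13 without AKR_F1 replicate 2). Of 12 class II genes 2 passed over all genes, and adjusted over the list alone 3 were higher in DBA_F1 and 1, cathepsin S (Ctss), in AKR_F1. Their mean was -0.26 (camera adjusted p = 0.034, and adjusted p = 0.709 with an estimated correlation), with adjusted p = 0.177 without AKR_F1 replicate 2, and the call was also lost without AKR_F1 replicate 1 or DBA_F1 replicate 1. With the upper airway and oesophagus mean as a covariate the class II mean was -0.053 (adjusted p = 0.829), and for AKR_F1 replicate 3 alone against DBA_F1 it was -0.060. Among 13 class I and peptide loading genes H2-Q10 was higher in AKR_F1 and H2-K1 in DBA_F1 (-0.28 ± 0.043, adjusted p = 0.0232, and 0.0985 without AKR_F1 replicate 2, lost also without AKR_F1 replicate 1 or DBA_F1 replicates 2 or 3), and adjusted over the list alone 6 were higher in AKR_F1 and 3 in DBA_F1. That list was not called (mean 0.17, adjusted p = 0.24). It was called with the upper airway and oesophagus covariate (0.28, adjusted p = 0.00766), a fit close to AKR_F1 replicate 3 alone against DBA_F1 (0.28). With the replicate block H2-K1 (0.0542) and H2-Eb1 (0.0679) were not called, nor was H2-K1 without a trend (0.0684), and with quantile normalization the class II list was not (0.0582). The 8 tested probe sets of H2-D1 ranged from -5.65 ± 0.091 to 6.07 ± 0.21, with adjusted p of 8.27e-07 and 5.93e-05 (for the latter the DBA_F1 mean of 4.48 lay below the filter level, so its size is not exact), while its brightest differed by -0.18 (adjusted p = 0.0705).

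**Figure D3:**
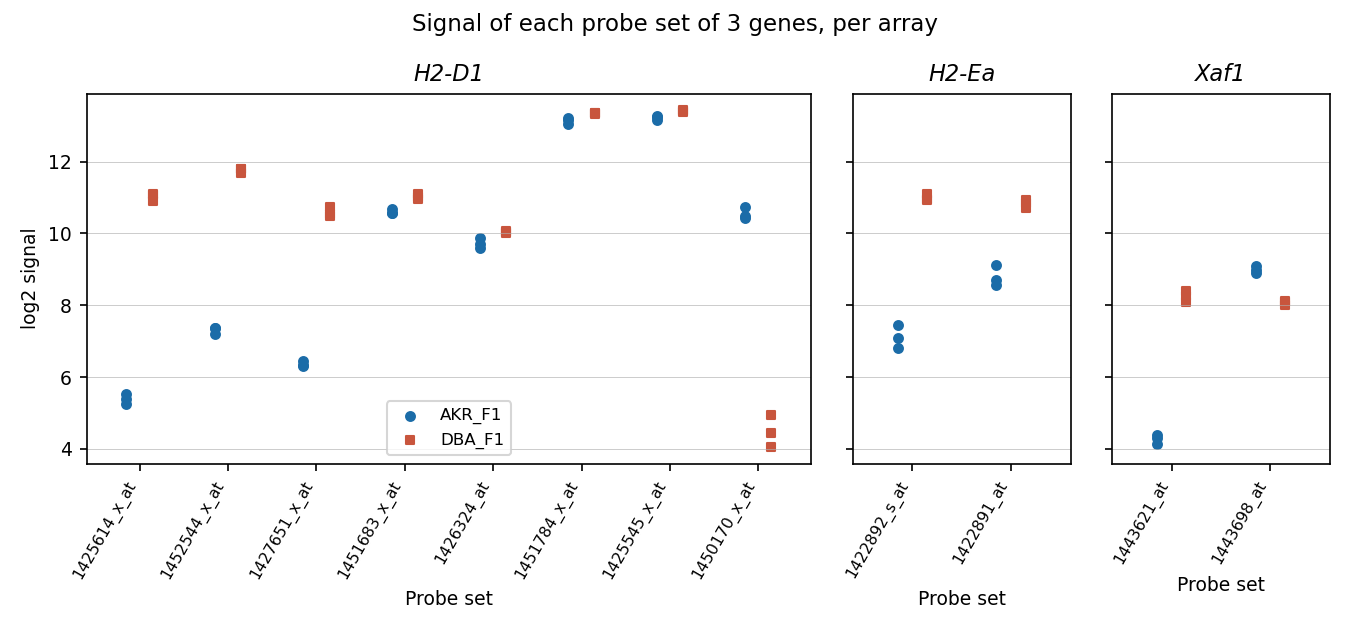
Log2 signal (vertical axis) of each tested probe set (horizontal axis) of H2-D1, H2-Ea and Xaf1 on the 3 AKR_F1 arrays (blue circles) and the 3 DBA_F1 arrays (red squares). H2-D1 and Xaf1 have probe sets in both directions, from -5.65 to 6.07 and from -3.97 to 0.92, and both probe sets of H2-Ea are higher in DBA_F1.

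T cell, thymus and cell cycle genes were higher in AKR_F1 as lists, mainly on AKR_F1 replicate 3. T cell genes had a mean difference of 0.43 (13 genes, camera adjusted p = 0.00695), cell cycle genes 0.26 (18 genes, adjusted p = 0.00899) and thymus genes 0.89 (4 genes, adjusted p = 0.0353). The adjusted p was 0.709 for each with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Cd8a had a signal of 7.90 in AKR_F1 replicate 3, 6.43 and 5.70 in AKR_F1 replicates 1 and 2 and a mean of 5.44 in DBA_F1, and the thymocyte enzyme terminal transferase (Dntt) had 7.83, 5.86, 4.79 and 4.52 in the same order. Rag1, a thymus gene left out by the filter, had 8.55 in AKR_F1 replicate 3 and 6.51 in AKR_F1 replicate 1. It had 3.075 in AKR_F1 replicate 2 and a mean of 2.915 in DBA_F1. Prss16 (6.93) and Arpp21 (5.735), also left out, were highest in AKR_F1 replicate 3, while Foxn1 (4.23), Ptcra (4.04) and Psmb11 (3.80) stayed low there. Thymus tissue in the collected pieces was not tested as a source. Without AKR_F1 replicate 3 the mean was 0.43 for thymus genes, which were still called (adjusted p = 0.0474). It was 0.16 for T cell genes (adjusted p = 0.109) and 0.12 for cell cycle genes (adjusted p = 0.172). Cell cycle genes were also not called with the 60% filter (0.0664), nor T cell (0.0658) or thymus genes (0.0876) with array weights. With the upper airway and oesophagus mean as a covariate the means were larger, 1.002 for T cell, 0.55 for cell cycle and 1.81 for thymus genes. They were close to those of AKR_F1 replicate 3 alone against DBA_F1 (0.98, 0.55 and 1.81). B cell and plasma cell genes were not called over all 6 arrays (mean 0.027). Their mean on AKR_F1 replicate 3 was also above that of AKR_F1 replicates 1 and 2 (0.34). With this covariate they were called (0.29, adjusted p = 0.00142), with 0.25 for AKR_F1 replicate 3 alone against DBA_F1. T cell genes were also not called without DBA_F1 replicate 1, nor thymus genes without DBA_F1 replicate 1 (0.12) or DBA_F1 replicate 3.

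Interferon-response genes had a mean difference of 0.12 toward AKR_F1 (28 genes, camera adjusted p = 0.00899, and adjusted p = 0.709 with an estimated correlation). The call was lost without AKR_F1 replicate 3 (0.0914) or DBA_F1 replicate 3. Only Xaf1, an interferon-induced apoptosis regulator, passed over all genes (0.92 ± 0.066, adjusted p = 0.00109), but its other tested probe set differed by -3.97 (adjusted p = 9.94e-06), a size that is not exact since its AKR_F1 mean of 4.27 lay below the filter level. With the mean of the probe sets of each gene the list mean was 0.034 and the list was not called (adjusted p = 0.12). Adjusted over the list alone 4 passed, the others being Ifit1 (0.46), Rtp4 (0.38) and Ifih1 (0.30). Of 12 alveolar macrophage genes Siglecf, a sialic acid-binding receptor of alveolar macrophages and eosinophils, was higher in AKR_F1 (0.83 ± 0.12, adjusted p = 0.0182) and Cidec in DBA_F1. Adjusted over the list alone 2 were higher in AKR_F1 and 1 in DBA_F1, and the list was not called (mean -0.061, median 0.062 and camera direction toward AKR_F1, adjusted p = 0.819). In the list of 30 metastatic niche genes the adhesion molecule Icam1 (0.32 ± 0.054, adjusted p = 0.0324) and the macrophage growth factor receptor Csf1r (0.23 ± 0.042, adjusted p = 0.0439) were higher in AKR_F1. Adjusted over the list alone 5 were higher in AKR_F1 and 1 in DBA_F1, and the list was not called (mean -0.094, adjusted p = 0.819). Csf1r lost its call in each fit that left out 1 array (0.169 without DBA_F1 replicate 2), Icam1 without AKR_F1 replicate 1 (0.144), AKR_F1 replicate 2 or DBA_F1 replicates 2 or 3, and Siglecf without DBA_F1 replicate 2 (0.0879), DBA_F1 replicate 1 or AKR_F1 replicate 1. With the replicate block Icam1 (0.0627) and Csf1r (0.11) were not called, nor without a trend (0.0681 and 0.102). Csf1r was not called without a filter (0.0586) or with the mean of its probe sets (0.159).

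Xenobiotic metabolism genes were higher in DBA_F1 as a list, with a mean of -0.29 and a median of -0.11 over 34 genes (camera adjusted p = 1.08e-06, and adjusted p = 0.709 with an estimated correlation). The ethanol-metabolising Cyp2e1, which adipocytes also express, and the carboxylesterase Ces1f (-0.84 ± 0.11, adjusted p = 0.0142) passed over all genes and adjusted over the list alone. Ces1f had an adjusted p of 0.0662 without DBA_F1 replicate 2, lost its call also without AKR_F1 replicates 1 or 2, while Cyp2e1 had 0.0508 without AKR_F1 replicate 2. The aldehyde dehydrogenase Aldh3a1 had -1.49 ± 0.51 (adjusted p = 0.191), with 9.71 in AKR_F1 replicate 3 against 7.63 and 8.04 in AKR_F1 replicates 1 and 2, as the squamous genes had. Glucocorticoid-response genes had a mean of -0.44 (12 genes, adjusted p = 0.0321, and adjusted p = 0.763 with an estimated correlation), with 0 passing over all genes and 1, the pyruvate dehydrogenase kinase Pdk4 (-1.68 ± 0.33), adjusted over the list alone. The mean was -0.23 without DBA_F1 replicate 3 (adjusted p = 0.455), -0.26 without AKR_F1 replicate 1 and -0.78 without DBA_F1 replicate 1, and the call was lost without the first pair or DBA_F1 replicate 2. With the upper airway and oesophagus mean as a covariate it was -0.17 (adjusted p = 0.541), and the adjusted p was 0.055 with quantile normalization and 0.086 with the mean of the probe sets of each gene. Unfolded protein and heat shock genes had a mean of 0.23 toward AKR_F1 (18 genes, adjusted p = 0.0141, and adjusted p = 0.709 with an estimated correlation), with 0 passing by either count. Hspa1a had 10.37 in AKR_F1 replicate 3 and 6.76 and 7.62 in AKR_F1 replicates 1 and 2, and the call was lost without AKR_F1 replicate 3 (mean 0.11) or DBA_F1 replicate 1 (mean 0.15, adjusted p = 0.196). With the adipose mean as a covariate the direction turned (mean -0.063), and with the upper airway and oesophagus mean it was 0.50.

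Among 12 mouse metastasis modifier genes none passed over all genes. Nup210, a nuclear pore gene, had the largest difference (0.40 ± 0.083, adjusted p = 0.06) and was the 1 gene that passed adjusted over the list alone. Cadm1 had 0.23 ± 0.088 (adjusted p = 0.233), Sipa1 0.12 ± 0.066 (adjusted p = 0.391) and Rrp1b 0.10 ± 0.074 (adjusted p = 0.514). The list had a mean of 0.096 and was not called (camera adjusted p = 0.0632). It was called with the upper airway and oesophagus mean as a covariate (0.11, adjusted p = 0.0404), a fit close to AKR_F1 replicate 3 alone against DBA_F1 (0.11). Of 11 genes with known null, structural or copy number alleles in a parental strain, H2-Ea and Gpnmb passed. Membership of this list does not tie a difference to a known allele. An allele of FVB/NJ is carried by both groups and cannot by itself separate them. The alleles of H2-Ea were not examined. Gpnmb, a melanosome and macrophage glycoprotein that carries a premature stop codon in DBA/2J, was 1.78-fold higher in AKR_F1 (0.84 ± 0.088, adjusted p = 0.0063). With the upper airway and oesophagus mean as a covariate it differed by 0.83 and was not called (adjusted p = 0.0607). Klrd1, the CD94 subunit that NK cells of DBA/2J lack, had 0.23 ± 0.11 (adjusted p = 0.322), and Myo5a, mutated at the dilute locus of DBA/2J, had 0.10 ± 0.071 (adjusted p = 0.495). Adjusted over the list alone 1 was higher in AKR_F1 and 2 in DBA_F1, and the list was not called (mean -0.064, median 0.10 and camera direction toward AKR_F1, adjusted p = 0.819).

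The other lists were not called by camera. Mean differences and adjusted p were -0.097 and 0.0974 for 27 matrix and fibroblast genes, -0.38 and 0.129 for 12 heart muscle genes, -0.24 and 0.24 for 12 neutrophil and monocyte genes and 0.15 and 0.425 for 16 immediate early genes. They were -0.030 and 0.781 for 10 housekeeping genes, -0.050 and 0.819 for 4 erythroid genes, 0.021 and 0.819 for 11 NK cell genes, 0.027 and 0.873 for 14 circadian clock genes and 0.027 and 0.971 for 13 B cell and plasma cell genes. With the upper airway and oesophagus mean as a covariate the matrix and fibroblast genes (-0.086, adjusted p = 0.0371) and the immediate early genes (0.50, adjusted p = 0.0016) were called as well. For AKR_F1 replicate 3 alone against DBA_F1, on which that fit largely rests, the means were -0.11 and 0.54. The median had the opposite sign to the mean for housekeeping (0.0031), erythroid (0.019) and clock genes (-0.0095), and the camera direction was opposite to the mean for NK cell genes. None of their members passed over all genes or adjusted over the list alone. In all, 18 of 32 lists were called with the preset correlation, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 by fry.

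Different probe sets of a called gene mostly had the same sign, but most of the others did not pass. The 152 called genes with more than 1 tested probe set had 254 other probe sets. Of these, 83.9% had the same sign as the called one, against 68.9% of 9716 for genes not called (Fisher's exact test, p = 8.8e-08). That test counts probe sets of the same gene as independent. Called genes were also selected for a clear difference, so part of their higher share is built in. Of the 254 other probe sets, 61 (24%) also passed in the same direction, and 7 passed in the opposite direction (Camk2n1, H2-Q5, Nbeal1, Pdxdc1, Prrc2c, Xaf1 and Zfp945). By chromosome (GRCm38.p6 assignments), 0 of the Fisher's exact tests passed after adjustment, and 3 had an unadjusted p under 0.05. The lowest adjusted p was 0.0584, for chromosome 1 with 31 of 754 genes called (4.11%) and for chromosome 8 with 7 of 710 (0.986%). The 3' minus 5' log2 signal was 0.38 ± 0.10 (SD, n = 3) in AKR_F1 and 0.36 ± 0.020 in DBA_F1 for actin, and -0.30 in both groups for Gapdh (exact two-sided permutation p = 0.9 for each).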

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

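The covariate fits and the fit of AKR_F1 replicate 3 alone were chosen after seeing the data, and the other alternatives before. Of 37 passing named genes under the alternatives, 510 comparisons kept direction and call, 179 kept direction only and 2 reversed. For the called lists these numbers were 273, 79 and 5. Depending on the array left out, 198 to 1171 probe sets were called (105 to 561 higher in AKR_F1, 93 to 610 higher in DBA_F1) and 83 to 656 genes (41 to 274 and 39 to 382). A fit without 1 array has fewer samples. Array weights gave 1198 probe sets (717 higher in AKR_F1, 481 in DBA_F1) and 592 genes (352 and 240), and the cause was not tested. Quantile normalization, median centring, either filter, eBayes without a trend or robust, and the replicate block gave counts within 1.5 times the reported ones, but not always the same calls. Of the 37 named calls, 8 ended without a trend, 6 with the replicate block, 5 with robust eBayes, 2 without a filter, 1 with quantile normalization and 1 with median centring. Quantile normalization also ended 2 list calls, the 60% filter 1 and array weights 3, and the mean of the probe sets of a gene ended 5 named calls and 2 list calls. The adipose covariate ended 33 of the 37 named calls and the upper airway and oesophagus covariate 20. The 37 include members of the lists behind these covariates (Pck1, Fabp4, Adipoq and Lep for the first, Ltf for the second). For such members a loss is partly built in. Leaving out AKR_F1 replicate 1, AKR_F1 replicate 2, AKR_F1 replicate 3, DBA_F1 replicate 1, DBA_F1 replicate 2 and DBA_F1 replicate 3 ended 15, 17, 3, 10, 16 and 9.

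With the upper airway and oesophagus mean as a covariate, 188 probe sets (127 higher in AKR_F1, 61 in DBA_F1) and 81 genes (55 and 26) were called, 123 of the probe sets shared with the 707. With the adipose mean, 13 probe sets (5 and 8) and 4 genes (2 and 2) were called. For AKR_F1 replicate 3 alone against DBA_F1, with its spread assumed to be that of the other group, 85 probe sets (57 and 28) and 34 genes (24 and 10) were called. Over the 707 probe sets the median absolute log2 difference was 0.60, and 0.58, 0.59 and 0.57 in these fits, while the median SE rose from 0.0816 to 0.117, 0.175 and 0.116. Some differences also shrank with the first covariate, such as Lpcat1 (0.41 to 0.28), Napsa (0.34 to 0.24) and H2-Eb1 (-0.81 to -0.52), and the cause for single calls was not tested.

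Reversed means were -0.0084 (endothelial) and 0.62 (skeletal muscle) with the upper airway and oesophagus covariate, 0.50 (skeletal muscle) for AKR_F1 replicate 3 alone, and 0.027 (oxidative phosphorylation) and -0.063 (unfolded protein and heat shock) with the adipose covariate. Sipa1 was -0.015 with the adipose covariate. Xaf1 was -1.53 as the mean of its probe sets and -3.97 by the most variable one, since its probe sets differ in direction. The other causes were not tested. Of 32 lists, 0 were called by camera with an estimated correlation and 0 by fry. Each covariate gives no value for its own list. Other probe sets had the sign of the called one in 81.3% without a filter and 84.7% with the 60% filter, and 0 chromosomes passed in any counting. The pseudocount alternatives were not run, since the values are log2. Over all tested probe sets replicate numbers did not pair the arrays (correlations of residuals 0.311, -0.228 and -0.0497 for equal numbers). Some lists did follow the replicate number in both groups. The immediate early mean was 9.13, 9.31 and 9.81 on AKR_F1 replicates 1 to 3 and 8.87, 9.22 and 9.70 on DBA_F1 replicates 1 to 3. The glucocorticoid-response mean was 9.05, 9.48 and 9.65, and 9.14, 10.09 and 10.25. An effect of collection order shared by the groups was not tested. Low signals lie near an unstated background, which limits what weak probe sets can show.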

Other observations

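The tests on splits of the arrays, oesophagus, parental genotype, a wrong label and genotype against dissection were chosen after the results were seen. The atrial peptide gene Nppa had a signal of 12.17 in DBA_F1 replicate 1 and 6.74 to 7.85 on the other arrays, and the mean of the 12 heart muscle genes was 10.49 there and 9.11 to 9.42 elsewhere. Hspa1b had 11.91 in AKR_F1 replicate 3, against 8.99 and 10.16 in AKR_F1 replicates 1 and 2 and 8.34 to 10.22 in DBA_F1. Neighbouring called genes included Vnn3 and Vnn1 (-0.95 and -0.73), Acoxl and Bcl2l11 (0.97 and 0.76) and Zfp945 and Zfp40 (0.91 and 0.65). There were 13 such pairs, 8 of the same sign, against a mean of 8.06 in 10000 random placements (permutation test, p = 0.0643). Of the 10 splits of the 6 arrays 1, the real one, called as many as 707 probe sets, and the highest other called 1. With 10 splits a share under 0.05 is not possible.

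Squamous epithelium transcripts were high on 4 of 6 arrays, on both sides of the group comparison. Parental genotype as the whole source is argued against by AKR_F1 replicate 3, whose list mean lay 3.01 log2 above AKR_F1 replicates 1 and 2. A DBA_F1 lung under a wrong label is argued against by the 1171 probe sets called without AKR_F1 replicate 3. On that array 683 of them (58.3%) lay nearer to the other AKR_F1 arrays and 488 nearer to DBA_F1. Squamous and muscle genes, whose list means on AKR_F1 replicate 3 lay near DBA_F1, were not left out of this count. Skin or hair is argued against by a median of 0.0192 over 14 skin and hair genes, for AKR_F1 replicate 3 against AKR_F1 replicates 1 and 2. Oesophagus in the collected piece, whose wall holds striated muscle in the mouse, may be the source, since the median of 11 skeletal muscle genes differed by 4.02 log2 in the same contrast. Squamous epithelium and muscle from other sites were not tested.

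Adipose genes were higher on each DBA_F1 array, with a gap of 0.528 log2 between the nearest list means of the groups. More fat in the collected DBA_F1 pieces may be a source. A second list of 19 adipose genes had a median of -0.70 (18 higher in DBA_F1), between the bounds set for it. The 9 brown fat genes had -1.40 (8 higher in DBA_F1), past the bound set for brown fat, although Ucp1 and Cidea are in the first list too. The first adipose list had a median of -1.76. That bound had no contrast with other fat, so it cannot tell brown fat from fat in general. Oxidative phosphorylation genes, abundant in brown fat, went from a mean of -0.26 to 0.027 with the adipose covariate. Since that covariate separates the groups completely, this value cannot decide the source. Within DBA_F1 both list means were lowest in replicate 3 (adipose 8.70, oxidative phosphorylation 10.87). From AKR_F1 replicate 1 to replicate 3 the adipose mean fell from 8.17 to 7.10, with oxidative phosphorylation at 10.82 and 10.84. Dissection that differed by group and a difference between the genotypes cannot be told apart, since adipose signal goes with group on all arrays.

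Some genes had called probe sets that disagreed, such as the called gene Pdxdc1 (0.87 and -3.98) and H2-D1 (-5.65 to 6.07), whose brightest probe set was not called. The lower group mean was below the filter level for the -3.98 and the 6.07, so these sizes are not exact. A sequence variant of a parental strain under the probes may be a source for part of the calls. Over the called genes the other probe sets had a median of 0.592 of the called difference, between the bounds set in advance, so that variants and expression cannot be told apart for the genes as a set, without probe sequences. Of the other probe sets 83.9% shared the direction, against 68.9% for genes not called, and 24% also passed in that direction. A difference in expression fits the genes whose probe sets agree. Called genes were selected for a clear difference, so their higher share of agreeing signs is partly built in and cannot decide this. Agreement does not tell the genotypes from other tissue in the pieces, since all probe sets were read on the same arrays.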
